A study of Sus scrofa with 32 samples.

How the data were processed

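Messenger RNA of the testis was sequenced from 32 male pigs, Danish crossbreds of Duroc with Landrace and Yorkshire, slaughtered at about 100 kg. Per the labels' protocols, RNA was isolated with a Qiagen kit and libraries were made with the TruSeq stranded mRNA kit. The deposited files hold 1 table of read counts per pig, with whole-number counts per Ensembl gene identifier and no normalization by the authors. Trimmomatic 0.33, cutadapt 1.8.1, STAR, SAMtools 1.3.1 and HTSeq 0.6.0 are the tools that the submitters' processing notes name. The genome build, the annotation release, the strand setting of the counting and the version of STAR were not given in the sources used here, so overlapping and antisense genes could not be separated and no coordinates are printed.

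Each table held 25322 gene identifiers and 5 closing rows for reads given to no gene. Those 5 rows stayed out of library sizes and tests. Reads in no annotated gene made up 20.6% to 39.6% of the reads of a library, unaligned reads 6.02% to 10.9%, reads with more than 1 alignment 5% to 6.63%, ambiguous reads 0.02% to 0.04% and reads of low alignment quality 0.02% to 0.08%. Symbols were taken from a table that pairs identifiers with symbols, which named 11804 of the 25322. Of 12 genes that were to be named in every androgen comparison, 8 had an identifier under their symbol; STAR, HSD3B1, CYP19A1 and SULT2A1 had none and were not analysed here. GZMA was the 1 symbol carried by more than 1 identifier.

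Groups were taken from the labels. High AS and Low AS are the submitters' names, and the labels expand AS as androstenone and skatole. Pigs had either a control diet or a diet with 15% chicory for 3 days before slaughter. There were 10 High AS pigs on control diet, 7 High AS pigs on chicory, 7 Low AS pigs on control diet, 7 Low AS pigs on chicory, and 1 pig on chicory without an AS group. That pig entered the fit of the sire breeding value and 1 alternative of the diet comparison. Replicate numbers within a group follow accession order and pair no pigs. The labels also give each pig's sow (14 sows, of which 7 had pigs in both AS groups), the sire's breeding value for androstenone (12 distinct values) and, for 29 pigs, the carcass weight. Fits with carcass weight as a covariate used only those 29 pigs. Skatole was given for 12 pigs and was not tested.

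Library names split the pigs into 8 numbered libraries and 24 plain libraries, a division called library set here. The numbered libraries held 10585625 to 20349500 counts in genes and the plain ones 1855174 to 5993637. Of the 8 numbered libraries 6 came from High AS pigs, and the 4 libraries of lane 7 all came from High AS pigs. Library set was therefore a term in every main model. Library pairs within a group were compared by chi-square over genes with at least 10 counts in the pair. The smallest of 108 values was 7.24 per degree of freedom, so no 2 libraries of the same group agreed within sampling noise.

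Main tests used edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, libraries were scaled with the trimmed mean of M values (TMM), and each coefficient was tested with the quasi-likelihood F test (glmQLFit and glmQLFTest) and Benjamini-Hochberg adjustment at 0.05. The AS comparison fitted AS group, diet and library set to 31 pigs. The androstenone comparison replaced AS group by the log2 of the concentration plus 0.5 mg/kg, so that a slope is the log2 change per doubling of that sum. The diet comparison used the model of the AS comparison. The interaction and the AS effect within each diet came from 1 model with a term for each combination. The sire breeding value was fitted as a number with diet and library set to all 32 pigs. Standard errors (SE) are the log2 fold divided by the square root of F. Levels are in CPM, edgeR's counts scaled to library size with TMM, and group values are means ± SD.

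Lists fixed before the data were examined were tested with fry in limma 3.58.1 on voom weights, which asks whether members move on balance one way. They held genes of steroidogenesis, steroid sulfation and conjugation, cholesterol synthesis and uptake, iron and ferritin, glutathione and NRF2 response, xenobiotic cytochromes and receptors, mitochondrially encoded genes, interferon response, immediate early and heat shock genes, and markers of Leydig cells, Sertoli cells, spermatogonia, spermatocytes, round spermatids, elongating spermatids, peritubular and smooth muscle cells, endothelium, macrophages and immune cells, blood cells and epididymis, 20 lists in all. Alternatives were camera with a preset correlation of 0.01 and camera with an estimated correlation. Adjustment was over the 20 lists. Members were also counted after Benjamini-Hochberg adjustment over the list alone.

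The genes named were fixed by rule before the data were examined. Among genes with a symbol, the 10 rising and 10 falling genes with the smallest p past the threshold were to be named, all that passed where fewer did, and the 3 with the smallest p where none passed. In the AS and androstenone comparisons the 12 genes above were always named, and up to 4 members with the smallest p per list. Called genes without a symbol are given by identifier. Some genes that the rule names are not reported here. Pig traits were compared with two-sided permutation tests on the difference in means, exact where a group had under 10 pigs and all divisions could be listed and otherwise with 100000 resamples, in SciPy 1.17.1. These formed a family of 30 tests. Correlations across pigs are Pearson's r and Spearman's rho with permutation p values from 100000 resamples, in a family of 15 for genes and 4 for list means. Both families repeat the same relations in overlapping sets of libraries.

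Scripts were tested on simulated counts drawn from the real genes' means, dispersions and library sizes, with 100 genes changed 2-fold and 100 changed 1.5-fold in each comparison. In the AS comparison 83% and 44% of these were recovered, for diet 90% and 43%, for AS within control diet 58% and 13%, for AS within chicory 47% and 13%, and for the interaction 4% and 0%. For changes of 2-fold and 1.5-fold per SD of the predictor, 97% and 85% were recovered for androstenone and 100% and 90% for the sire breeding value. Unchanged genes called numbered 9 for AS, 8 for androstenone, 7 for diet and 10 for the sire breeding value. They numbered 3 for AS within chicory and 0 for AS within control diet and the interaction. Simulated pigs were drawn independently, with no sow, sire or library set effect, so recovery in the real pigs may differ. In 20 simulated runs a list of 25 genes shifted by 0.5 on the log2 scale was called 20 times, and 1 of 380 unchanged lists was called. Simulated genes were drawn independently and put into lists at random. These rates therefore need not hold for real lists whose members move together across pigs.

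Alternatives fixed before the data were examined were scaling by relative log expression, no low-count filter, a stricter filter on CPM of at least 1, DESeq2 1.42.0, limma voom, no library set term, index set in its place, plain or numbered libraries alone, leaving out lane 7, sow as a fixed block, sow as a random effect, carcass weight as a covariate, other scales or ranges of the concentration, and leaving out each pig in turn. Added after the data were examined were fits without 2 libraries that stood apart, fits with the Leydig marker level as a covariate, and an androstenone fit without the pigs recorded at 0 mg/kg.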

Results

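Gene expression was measured by RNA sequencing in the testis of 32 crossbred male pigs that differed in androstenone, a 16-androstene steroid made in the boar testis. Counts assigned to genes ranged from 1855174 to 20349500 per pig, with a median of 4061083, and 14999 to 18269 genes were detected per library. Of the 31 pigs with an AS group, 17 were High AS and 14 were Low AS, and 14 received chicory, a root feed rich in inulin, while 17 received the control diet. The series' design text names expression quantitative trait loci for androstenone as its subject. The comparisons it implies are High against Low AS, the androstenone concentration itself, chicory against control diet, their interaction, and the sire breeding value.

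High AS pigs carried 2.59 mg/kg ± 1.99 androstenone (SD, n = 17) against 0.54 mg/kg ± 0.405 in Low AS pigs (SD, n = 14). The labels call AS an androstenone and skatole group, so a p value of this difference would restate the grouping and is not given. High AS pigs ranged from 0.67 to 7.77 mg/kg and Low AS pigs from 0 to 1.07 mg/kg. The overlap came from High AS control replicate 5 alone, at 0.67 mg/kg, as all other High AS pigs had 1.09 mg/kg or more. Its skatole, 0.615 mg/kg, was the highest of the 12 pigs with a value. Means were 2.64 against 0.59 mg/kg within control diet (n = 10 and 7) and 2.51 against 0.49 mg/kg within chicory (n = 7 and 7). Androstenone on chicory was 1.5 mg/kg ± 1.61 (SD, n = 14) and on control diet 1.8 mg/kg ± 1.99 (SD, n = 17; permutation p = 0.67, adjusted p = 0.912 over 30 tests). Carcass weight was 91.7 kg ± 5.56 in 15 High AS pigs and 87.0 kg ± 5.1 in 14 Low AS pigs (permutation p = 0.027), which missed the threshold after adjustment (adjusted p = 0.202).

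Between High and Low AS testes, genes of cholesterol supply had the smallest p of the 20 lists, and no gene and no list passed its test. CYP4B1, a cytochrome P450 that hydroxylates fatty acids and foreign compounds, had 24.9 CPM ± 11.9 in High AS pigs (SD, n = 17) and 14.7 ± 9.25 in Low AS pigs (SD, n = 14), a log2 fold of 0.96 (SE 0.28, adjusted p = 0.988). It was the only list member below the threshold when adjusted over the list alone (0.0237), and SRD5A1, a steroid 5-alpha-reductase, had a log2 fold of 0.54 (SE 0.21), or 0.35 (SE 0.19) without High AS chicory replicate 3 and 0.29 (SE 0.24) with carcass weight as a covariate. SLC46A3, a lysosomal transporter, and PC, the pyruvate carboxylase that feeds the citric acid cycle, had log2 folds of 0.68 (SE 0.21) and 0.41 (SE 0.13). Among genes lower in High AS pigs the smallest p values belonged to FBXL16, NPR1, a natriuretic peptide receptor, and POLR1C, a subunit of RNA polymerases, with log2 folds of -0.78 (SE 0.22), -0.63 (SE 0.20) and -0.43 (SE 0.14). The edgeR test called 0 of 13025 genes, with 300 at an unadjusted p under 0.05, and limma voom and DESeq2 also called 0.

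The androgen pathway genes named in advance gave values without a call. CYP17A1, which makes androgens and 16-androstenes from pregnenolone, had 1060 CPM ± 674 in High AS pigs and 904 ± 675 in Low AS pigs, a log2 fold of 0.61 (SE 0.29) at an unadjusted p of 0.0424. CYP11A1, the side-chain cleavage enzyme, LHCGR, the luteinizing hormone receptor, and INSL3, a Leydig cell peptide hormone, had log2 folds of 0.42 (SE 0.27), 0.64 (SE 0.36) and 0.42 (SE 0.30). For CYB5A, the cytochrome b5 that acts with CYP17A1, the value was 0.14 (SE 0.21), and for FTL, the ferritin light chain, 0.24 (SE 0.18). HSD17B3, which reduces androstenedione to testosterone, and the Leydig cell transcription factor NR5A1 had -0.20 (SE 0.21) and -0.07 (SE 0.27). All 8 had an adjusted p of 0.988. Within library sets the CYP17A1 log2 fold was 0.32 (SE 0.29) in plain libraries and 1.75 (SE 0.59) in numbered ones, of which 2 were Low AS. It was 0.20 (SE 0.34) with no library set term and 0.34 (SE 0.33) with carcass weight as a covariate, where CYP11A1 had 0.13 (SE 0.30), INSL3 0.23 (SE 0.36) and FTL 0.02 (SE 0.22). With sow as a fixed block LHCGR had 1.05 (SE 0.46) and INSL3 0.76 (SE 0.31). Leaving out 1 pig gave 0.51 to 1.09 for LHCGR, 0.31 to 0.66 for CYP11A1, 0.25 to 0.60 for INSL3, 0.07 to 0.28 for CYB5A and -0.35 to -0.12 for HSD17B3. NR5A1 had -0.26 to 0.04, so its sign changed with single pigs.

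Of 27 tested genes of cholesterol synthesis and uptake, 25 had a higher estimate in High AS pigs, with a median log2 fold of 0.23 (fry p = 0.00542, adjusted p = 0.108). SOAT1, which esterifies cholesterol for storage, had 0.41 (SE 0.14), HMGCS1, an early enzyme of the mevalonate pathway, 0.39 (SE 0.16), and SQLE, the squalene epoxidase, 0.23 (SE 0.10). None of the 27 passed over the list alone. In plain libraries alone the list had fry p = 0.0841 (adjusted p = 0.963). Camera with a preset correlation called this list (adjusted p = 4.48e-12) and 6 lists in all, and with an estimated correlation it called 0 (adjusted p = 0.0838 for cholesterol).

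Germ cell lists pointed in different directions without a call. All 24 elongating spermatid markers had a higher estimate in High AS pigs (median log2 fold 0.20, fry p = 0.207, SPATA18 0.28, SE 0.20), as did 17 of 18 round spermatid markers (median 0.09, p = 0.378). Of 10 spermatogonia markers 8 were lower (median -0.28, p = 0.226), among them the receptor genes RET at -0.66 (SE 0.37) and KIT at -0.42 (SE 0.24). Low AS chicory replicate 1 was below all other libraries for both spermatid lists (means of 7.22 and 5.99 log2 CPM) and above all others for spermatogonia (4.64). Without it RET had -0.23 (SE 0.26) and KIT -0.15 (SE 0.16). Without it and High AS control replicate 3, a choice made after the data were seen, 20 of 24 elongating spermatid markers (median 0.12, p = 0.464), 14 of 18 round spermatid markers (median 0.05, p = 0.77) and 2 of 10 spermatogonia markers (median -0.13, p = 0.276) were higher. Spermatocyte markers were lower in 15 of 25 (p = 0.899) and Sertoli markers in 10 of 16 (p = 0.64). Leydig markers were higher in 8 of 14 (median 0.17, p = 0.249), with VCAM1, a cell adhesion molecule, at 0.68 (SE 0.25) and IGF1 at -0.55 (SE 0.25). Endothelial markers were higher in 7 of 10 (median 0.17, p = 0.254), including the vascular growth factor receptors FLT1 at 0.37 (SE 0.15) and KDR at 0.45 (SE 0.24), or 0.12 (SE 0.31) with sow as a fixed block.

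The other lists between AS groups had fry p values of 0.105 or more. Higher estimates were found for 8 of 13 steroidogenesis genes (p = 0.301), 6 of 10 sulfation and conjugation genes (p = 0.487), 9 of 14 iron and ferritin genes (p = 0.211), 7 of 16 glutathione and NRF2 genes (p = 0.734), 8 of 13 xenobiotic cytochromes and receptors (p = 0.235), 11 of 17 interferon response genes (p = 0.874), 10 of 15 immediate early and heat shock genes (p = 0.105), 6 of 11 peritubular markers (p = 0.775), 4 of 11 macrophage markers (p = 0.754), 3 of 4 epididymis markers (p = 0.497) and 0 of 13 mitochondrially encoded genes (p = 0.82). The single tested blood marker, HBB, had a log2 fold of -0.38 (SE 0.34, fry p = 0.391). For glutathione genes the median (-0.04) and the direction of the test (up) differed in sign, and the peritubular median was 0 with a downward test. Without Low AS chicory replicate 1 and High AS control replicate 3, 9 of the 13 mitochondrially encoded genes were higher (median 0.10, p = 0.754).

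**Figure D1:**
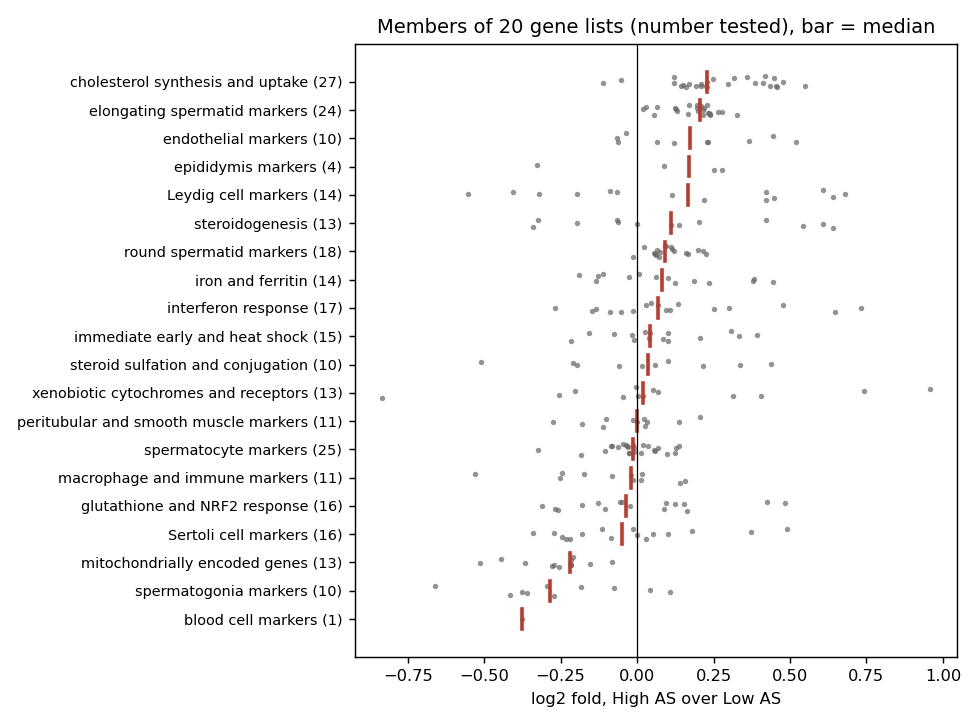
Log2 fold between High and Low AS pigs for each tested member of the 20 lists (points), with the number tested beside the list name and the median as a bar. The cholesterol list has the highest median, 0.23, with 25 of 27 members above 0.

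Along the androstenone concentration, 2 named genes rose and 1 gene without a symbol fell in testis. SRD5A1, whose enzyme class carries out the 5-alpha reduction in androstenone synthesis, rose by 0.44 per doubling of the concentration plus 0.5 mg/kg on the log2 scale (SE 0.08, n = 31, adjusted p = 0.0343). CYP4B1 rose by 0.69 (SE 0.12, adjusted p = 0.0113). ENSSSCG00000021574 fell by 2.97 (SE 0.44, adjusted p = 0.00121). These 3 were the genes called of 13199 tested, with 668 at an unadjusted p under 0.05. All 3 calls ended with other model terms, given in the order SRD5A1, CYP4B1 and ENSSSCG00000021574. With index set the slopes were 0.43 (SE 0.10), 0.65 (SE 0.14) and -2.97 (SE 0.59), with adjusted p of 0.506, 0.313 and 0.223. With no library set term they were 0.40 (SE 0.09), 0.57 (SE 0.14) and -1.63 (SE 0.37), with 0.158, 0.338 and 0.172. With carcass weight they were 0.38 (SE 0.10), 0.65 (SE 0.15) and -3.47 (SE 0.62), with 1, 0.471 and 0.0527. That fit also lacked High AS control replicate 1 and High AS chicory replicate 4, which have no carcass weight. With the rank of the concentration adjusted p was 0.274, 0.0632 and 0.0632, and with the untransformed concentration it was 0.687 for SRD5A1 and 0.819 for CYP4B1. SRD5A1 also did not pass with limma voom (0.113), with sow as a random effect (0.154) and without the 2 highest concentrations (0.702), and CYP4B1 did not pass without lane 7 (0.0729). The falling genes with a symbol did not pass, and the smallest p values were those of FBXL16 (-0.44, SE 0.10), ABCB10, a mitochondrial transporter of the heme pathway (-0.47, SE 0.11), and TBC1D23 (-0.34, SE 0.08), with adjusted p from 0.164 to 0.267. With sow as a fixed block FBXL16 had -0.19 (SE 0.18) and ABCB10 -0.02 (SE 0.13), and ABCB10 had -0.27 (SE 0.11) with index set and -0.10 (SE 0.33) in numbered libraries alone.

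Single pigs ended the calls of CYP4B1 and SRD5A1, while ENSSSCG00000021574 passed in 31 of 31 fits that left out 1 pig. CYP4B1 had an adjusted p of 0.14 without High AS chicory replicate 3 and 0.0596 without Low AS chicory replicate 6, with slopes of 0.67 (SE 0.14) and 0.65 (SE 0.12). SRD5A1 passed in 18 of 31 fits that left out 1 pig, with slopes from 0.33 to 0.51. Its adjusted p was 0.824 without High AS chicory replicate 3, 0.179 without Low AS chicory replicate 6, 0.141 without Low AS control replicate 2, 0.133 without Low AS chicory replicate 7 and 0.0993 without High AS chicory replicate 2. It was 0.0504 to 0.0651 without High AS control replicate 1, High AS chicory replicates 4 and 5, Low AS control replicates 1 and 7, or Low AS chicory replicates 3, 4 and 5. Without the pigs recorded at 0 mg/kg, a choice made after the data were seen, no gene was called, with slopes of 0.35 (SE 0.10) for SRD5A1 and 0.49 (SE 0.12) for CYP4B1. The low-count filter removed ENSSSCG00000021574 from that fit, so it was not tested there. The stricter filter on CPM also removed it. With sow as a fixed block no gene was called, with slopes of 0.54 (SE 0.13) for SRD5A1, 0.66 (SE 0.14) for CYP4B1 and -0.14 (SE 0.49) for ENSSSCG00000021574. In plain libraries alone the slopes were 0.47 (SE 0.08) for SRD5A1 and 0.70 (SE 0.13) for CYP4B1, with adjusted p of 0.0438 and 0.0529, and in numbered ones 0.30 (SE 0.22) and 0.68 (SE 0.26), with 0.999 for both.

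**Figure D2:**
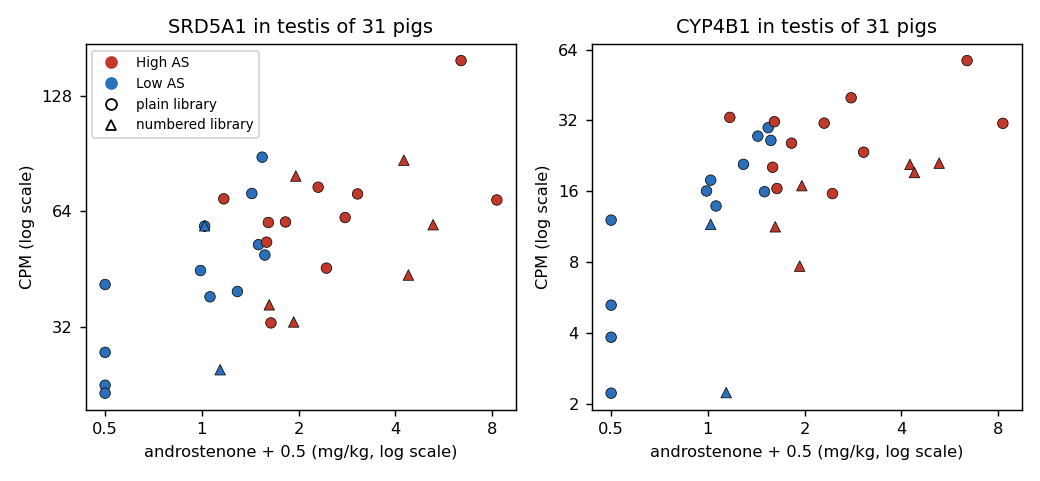
CPM of SRD5A1 and CYP4B1 (log axis) against the androstenone concentration plus 0.5 mg/kg (log axis) in 31 pigs, coloured by AS group and shaped by library set. Each point is 1 pig, and the slopes are 0.44 and 0.69 per doubling on the log2 scale.

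Across pigs, log2 CPM of 3 genes named in advance was correlated with log2 androstenone within library sets, without a relation that passed. In the 23 plain libraries r was 0.24 for INSL3 (permutation p = 0.28, rho = 0.14, permutation p = 0.52), 0.34 for CYP17A1 (permutation p = 0.11, rho = 0.29, permutation p = 0.18) and 0.36 for FTL (permutation p = 0.09, rho = 0.20, permutation p = 0.35), with 0.19, 0.47 and 0.37 without the 2 pigs farthest from the median. In the 8 numbered libraries r was 0.46 (permutation p = 0.25, rho = 0.43, permutation p = 0.3), 0.53 (permutation p = 0.18, rho = 0.57, permutation p = 0.15) and 0.66 (permutation p = 0.08, rho = 0.50, permutation p = 0.21), with 0.46, 0.72 and 0.58 without the 2 farthest. Adjusted p was 0.169 to 0.323 over 15 tests, which hold each gene in overlapping sets of libraries. Pooled over both sets r was 0.08, 0.13 and 0.32, which leaves out the difference between sets. SRD5A1 and CYP4B1 were chosen for their slope on the same concentration in the same pigs, so their correlations would restate that choice and are not given.

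Model slopes of the pathway genes named in advance did not pass either. They were 0.30 (SE 0.15) for CYP17A1, 0.23 (SE 0.14) for CYP11A1, 0.27 (SE 0.19) for LHCGR, 0.21 (SE 0.14) for INSL3, 0.12 (SE 0.11) for CYB5A, 0.22 (SE 0.09) for FTL, -0.21 (SE 0.10) for HSD17B3 and 0.002 (SE 0.13) for NR5A1, with adjusted p of 0.852 or more. Leaving out 1 pig gave 0.08 to 0.30 for INSL3, 0.18 to 0.38 for LHCGR, 0.07 to 0.20 for CYB5A and 0.17 to 0.35 for CYP11A1, with the lowest values of INSL3 and LHCGR without High AS chicory replicate 3. NR5A1 ranged from -0.05 to 0.05. With carcass weight CYP17A1 had 0.11 (SE 0.17) and CYP11A1 0.05 (SE 0.16), and with sow as a fixed block, where no gene passed, CYP17A1 had 0.58 (SE 0.22), LHCGR 0.78 (SE 0.29) and INSL3 0.66 (SE 0.18). Adjusted over the list alone, 5 list members passed: SRD5A1 (0.000101), CYP4B1, FMO1, a flavin monooxygenase (slope -0.68, SE 0.19, 0.00854), GSTO1, a glutathione transferase (0.35, SE 0.11, 0.0432), and VCAM1 (0.39, SE 0.12, 0.0408). With sow as a fixed block FMO1 had -0.07 (SE 0.25) and VCAM1 0.67 (SE 0.16). CYP2E1, a cytochrome P450 that metabolizes skatole in pig liver, had a slope of 0.32 (SE 0.14), or 0.14 (SE 0.11) without High AS control replicate 3, and did not pass over the list.

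No list moved as a whole with androstenone (fry, 0 of 20 called, smallest adjusted p = 0.426). Cholesterol synthesis and uptake had 23 of 27 positive slopes (median 0.09, p = 0.04), with FDPS, a synthase of the mevalonate pathway, at 0.14 (SE 0.05), SCARB1, the high-density lipoprotein receptor, at 0.26 (SE 0.12) and LSS, the lanosterol synthase, at 0.21 (SE 0.10), or 0.10 (SE 0.11) without High AS chicory replicate 3. Positive slopes were found for 23 of 24 elongating spermatid markers (p = 0.228, ODF2 0.17, SE 0.07), 12 of 18 round spermatid markers (p = 0.632), 10 of 25 spermatocyte markers (p = 0.468), 2 of 10 spermatogonia markers (p = 0.0631, KIT -0.24, SE 0.12), 5 of 16 Sertoli markers (p = 0.646) and 10 of 14 Leydig markers (p = 0.293). The counts were 9 of 13 for steroidogenesis (p = 0.192, CYB5R3 0.14, SE 0.06), 5 of 14 for iron and ferritin (p = 0.269, ALAS1 0.33, SE 0.13), 13 of 16 for immediate early and heat shock (p = 0.0639) and 11 of 13 for mitochondrially encoded genes (p = 0.178). The remaining 9 lists had p values between 0.361 and 0.989. Without Low AS chicory replicate 1 and High AS control replicate 3, spermatogonia markers had p = 0.0087 (adjusted p = 0.174) and mitochondrially encoded genes 13 of 13 positive slopes (p = 0.0377, adjusted p = 0.277). The iron list had a negative median (-0.02) and an upward test, as had the blood marker (-0.09). Camera with a preset correlation called 4 lists and with an estimated correlation 0, with a smallest adjusted p of 0.572.

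ENSSSCG00000021574 was read in some pigs and nearly absent in the others. At a threshold of 1 CPM it was detected in 8 of 32 pigs, at 2.62 to 8.61 CPM, and the other 24 pigs had at most 0.552 CPM. The 8 pigs came from 5 sows, and 6 of them were Low AS. Its slope with androstenone was -1.68 (SE 0.42, adjusted p = 0.423) with limma voom and -2.47 (adjusted p = 0.228) with DESeq2. With sow as a random effect it was -1.525 (SE 0.44, adjusted p = 0.953).

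Chicory feeding for 3 days left the testis transcriptome with 1 called gene. ENSSSCG00000028731, which has no symbol, rose to 1.84 CPM ± 1.75 on chicory (SD, n = 14) from 0.0574 ± 0.148 on control diet (SD, n = 17), a log2 fold of 4.63 (SE 0.63, adjusted p = 2e-04). No gene with a symbol passed. Small p values were those of PNCK, a calcium-dependent kinase (0.59, SE 0.19), HEY2, a target of Notch signalling (0.74, SE 0.27), and OOEP (0.94, SE 0.35) among higher genes, and LYVE1, the hyaluronan receptor of lymphatic vessels and some macrophages (-0.70, SE 0.25), and FAM200A (-0.47, SE 0.17) among lower ones. The edgeR test had 114 of 13025 genes at an unadjusted p under 0.05. Counts of ENSSSCG00000028731 are low, so that leaving out 1 of 5 chicory pigs (High AS replicates 4, 5 and 7, Low AS replicates 3 and 5) or using plain libraries alone removed it at the low-count filter. It was also filtered out, and so not tested, with the stricter filter, with no library set term and in 32 pigs without an AS term. Its adjusted p was 0.358 with limma voom and 0.0798 without lane 7.

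No list moved with diet (fry, 0 of 20 called). Immediate early and heat shock genes had 10 of 15 lower estimates on chicory (p = 0.0408, adjusted p = 0.817), with the stress-induced transcription factors ATF3 at -0.51 (SE 0.25, from -0.57 to -0.32 leaving out 1 pig) and FOS at -0.49 (SE 0.27, from -0.62 to -0.32) and the early response gene IER3 at -0.34 (SE 0.22). All 10 endothelial markers were lower (median -0.15, p = 0.265), including the receptors TIE1 at -0.30 (SE 0.20) and TEK at -0.42 (SE 0.32, from -0.53 to -0.25 leaving out 1 pig). Cholesterol genes were lower in 18 of 27 (p = 0.401), with INSIG1, which restrains sterol synthesis, at -0.34 (SE 0.16). Spermatogonia markers were higher in 8 of 10 (p = 0.329, RET 0.85, SE 0.35), and in 5 of 10 without Low AS chicory replicate 1 and High AS control replicate 3 (p = 0.463), with RET at 0.41 (SE 0.25) without the former alone. Higher estimates were found for interferon response genes in 14 of 17 (p = 0.636), macrophage markers in 7 of 11 (p = 0.517, TYROBP 0.53, SE 0.25) and round spermatid markers in 5 of 18 (p = 0.609). Iron and ferritin genes were higher in 7 of 14 (p = 0.353), with FECH, which inserts iron into heme, at -0.32 (SE 0.14). The other 12 lists had p values between 0.351 and 0.92, and the elongating spermatid and glutathione medians (0.04 and 0.01) had the opposite sign to their tests. Without Low AS chicory replicate 1 and High AS control replicate 3 these medians, 0.14 (22 of 24 higher, fry p = 0.248) and -0.02 (fry p = 0.797), matched their tests. The xenobiotic, round spermatid and peritubular medians were then negative with upward tests. Camera with a preset correlation called 4 lists and with an estimated correlation 0, with a smallest adjusted p of 0.185.

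**Figure D3:**
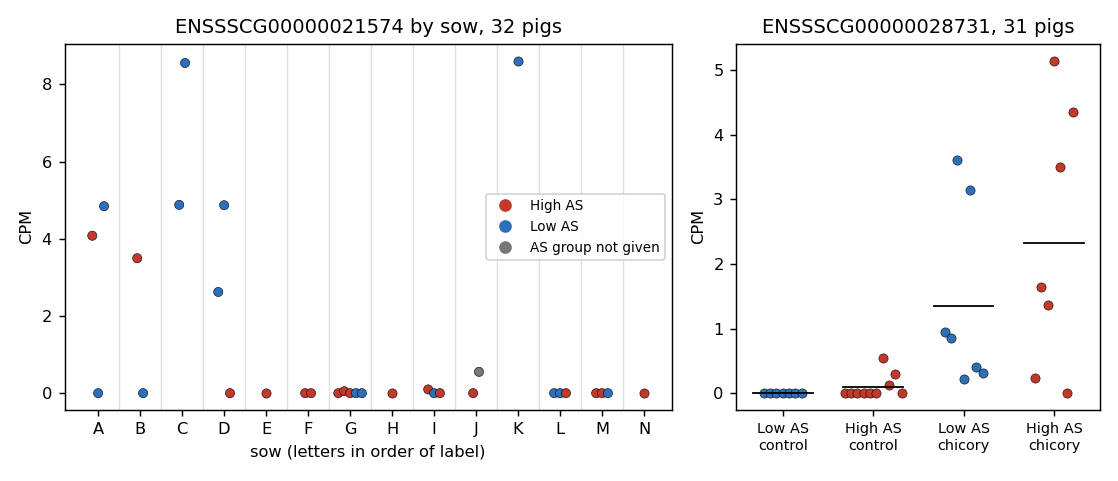
Left, CPM of ENSSSCG00000021574 in each of 32 pigs, grouped by sow and coloured by AS group, with the 8 detected pigs between 2.62 and 8.61 CPM. Right, CPM of ENSSSCG00000028731 in 31 pigs by AS group and diet, with group means as lines.

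No gene was called whose AS difference depended on diet, in a test that recovered 4% of simulated 2-fold changes. The interaction called 0 of 13025 genes in edgeR, with 473 at an unadjusted p under 0.05. PAX1, a developmental transcription factor (1.69, SE 0.46), ZNF276 (0.83, SE 0.24) and TCOF1, a nucleolar protein (0.72, SE 0.22), had the smallest p values among genes with a higher AS difference on chicory. ALB, serum albumin (-9.30, SE 2.05), SLC4A4, a bicarbonate cotransporter (-2.003, SE 0.53), and PLA2R1, a phospholipase A2 receptor (-1.67, SE 0.51), had the smallest in the other direction, with adjusted p of 0.944 or more. ALB stood at 1770 CPM in High AS control replicate 3, against a median of 6.05 in the other numbered libraries, and at 66 CPM in High AS control replicate 8. The median of plain libraries was 1.12 CPM. Without High AS control replicate 3 the ALB interaction was -2.72 (SE 0.88).

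Within control diet, High against Low AS called 0 genes, with 165 at an unadjusted p under 0.05. SLC46A3 (1.05, SE 0.26), ALB (4.56, SE 1.41, and 1.14, SE 0.57, without High AS control replicate 3) and TNFRSF12A, a receptor of the tumour necrosis factor family (1.07, SE 0.36), were highest by p among positive estimates, and DBNDD1 (-1.08, SE 0.34), LMOD2, an actin nucleator of muscle (-0.75, SE 0.27), and KBTBD12 (-0.99, SE 0.36) among negative ones. Within chicory, 0 genes were called and 810 had an unadjusted p under 0.05. All 7 Low AS pigs on chicory had plain libraries, while 3 of the 7 High AS pigs on chicory had numbered ones. The library set effect in this comparison and in the interaction was therefore estimated without Low AS chicory pigs. KRT4, an epithelial keratin (2.52, SE 0.73), ELL2, an elongation factor (0.51, SE 0.16), and CREBZF (0.78, SE 0.25) led the positive estimates, and LRRC39 (-1.19, SE 0.31), PLA2R1 (-1.34, SE 0.39) and NMI, an interferon-inducible protein (-1.07, SE 0.32), the negative ones, with adjusted p of 0.724. Without Low AS chicory replicate 1 NMI had -0.61 (SE 0.25). DESeq2 and limma voom also called 0 genes in the interaction and in both diets.

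The sire breeding value for androstenone was associated with 2 genes in 32 pigs. PHOSPHO2, a phosphatase of pyridoxal phosphate, rose by 1.58 per unit of breeding value on the log2 scale (SE 0.30, adjusted p = 0.0429), and ABCB10 fell by 2.20 (SE 0.38, adjusted p = 0.0175). Breeding values ranged from -0.49 to 0.36. The test covered 13009 genes, of which 1346 had an unadjusted p under 0.05. It counted pigs as replicates, although the 32 pigs held only 12 distinct breeding values. Its p values, those of the 2 called genes included, are therefore too small. Index set and breeding value went together. Breeding values spanned -0.49 to -0.10, -0.10 to 0.14 and 0.14 to 0.36 in the 3 index sets of the plain libraries, and index set held 0.63 of their variance (r squared) over all pigs. In plain libraries the association therefore cannot be told apart from a difference between index sets, while the 8 numbered libraries share 1 index set. With index set as a term neither gene passed: PHOSPHO2 had 1.95 (SE 0.49, adjusted p = 0.683) and ABCB10 -1.30 (SE 0.55, adjusted p = 1). In plain libraries alone PHOSPHO2 had 1.36 (SE 0.37, adjusted p = 0.884) and ABCB10 -2.32 (SE 0.46, adjusted p = 0.29), and in numbered ones PHOSPHO2 had 2.35 (SE 0.36, adjusted p = 0.0754) and ABCB10 -1.99 (SE 0.64, adjusted p = 0.318). ABCB10 passed in 29 of 32 fits that left out 1 pig, with adjusted p of 0.123 without High AS control replicate 8, 0.118 without Low AS chicory replicate 6 and 0.0598 without High AS chicory replicate 7. PHOSPHO2 passed in 18 of 32, with 0.123 without High AS control replicate 8, 0.111 without Low AS chicory replicate 6, 0.101 without Low AS control replicate 6 and 0.0849 without High AS chicory replicate 7. It had 0.0515 to 0.073 without the pig of no AS group, High AS control replicates 1, 2 and 10, High AS chicory replicate 2, Low AS control replicates 5 and 7, or Low AS chicory replicates 2, 3 and 4. Pigs of 1 sire share its breeding value, which the fits that left out 1 pig do not address. With pigs grouped by it as a random effect in limma voom PHOSPHO2 had 1.70 (SE 0.32, adjusted p = 0.0401) and ABCB10 -1.86 (SE 0.41, adjusted p = 0.116), and with sow as a random effect the adjusted p values were 0.0755 and 0.197.

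Cell type markers set 1 library apart. Low AS chicory replicate 1 had an elongating spermatid mean of 7.22 log2 CPM, against 8.9 to 10.5 in the other 31 libraries, and a round spermatid mean of 5.99, against 7.11 to 8.33. PRM1, a sperm protamine, stood at 659.6 CPM in it. Its spermatogonia mean (4.64), Sertoli mean (5.33) and macrophage and immune mean (3.03) were above all other libraries. Its mean of the 4 tested epididymis markers (1.99) was below all of them. Without this library and High AS control replicate 3, edgeR called 0 genes between AS groups, 4 for androstenone and 1 for diet.

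**Figure D4:**
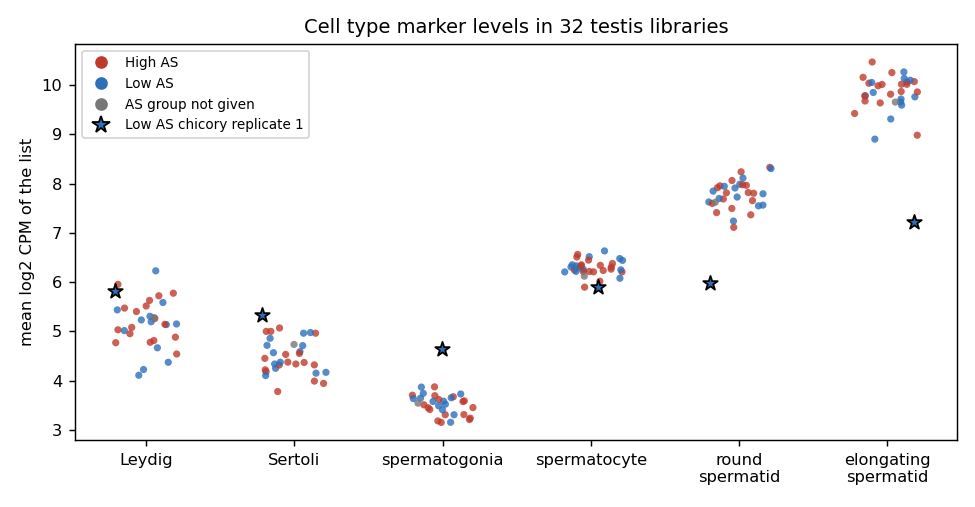
Mean log2 CPM of 6 cell type marker lists in each of 32 libraries, coloured by AS group, with Low AS chicory replicate 1 as a star. The star lies below all other libraries for round and elongating spermatid markers, at 5.99 and 7.22.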

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

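For Low AS chicory replicate 1, both tests of an explanation were chosen only after the result was seen, and for High AS control replicate 3 they were set beforehand. A sample was singled out here when its gap to the nearest sample, divided by the range of its group, was above Dixon's critical value. This held for 9 of 136 groups, over 34 measures, and chance gives about 1 in 20 groups.

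Low AS chicory replicate 1 gave 4 of the 9 values. Its gap was 0.814 of the range for elongating spermatid markers (7.22 log2 CPM, nearest pig 9.59), 0.734 for round spermatid markers (5.99, nearest 7.55), 0.673 for spermatogonia markers (4.64, nearest 3.75) and 0.827 for mitochondrially encoded genes (12.1, nearest 9.7). Low AS control replicate 5 was highest for LHCGR (gap 0.602, 4.27 log2 CPM, nearest 2.15) and for the steroid sulfation list (gap 0.688, 5.01, nearest 4.19). High AS chicory replicate 7 was lowest for NR5A1 (gap 0.581, 0.90 log2 CPM, nearest 1.92) and highest for elongating spermatid markers (gap 0.577, 10.5, nearest 10.1). High AS chicory replicate 4 was highest for the interferon response list (gap 0.62, 4.40, nearest 3.22).

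For the low spermatid levels of Low AS chicory replicate 1, RNA degradation or a failed library was weighed against fewer late germ cells in the sample. This library had the fewest gene counts (1855174) and genes detected (14999), the lowest assigned share (49.3%) and the highest share of reads in no annotated gene (39.63%) of all 32, but also the lowest shares of unaligned reads (6.02%) and of reads with more than 1 alignment (5%), so these values point both ways. Of the means of spermatocyte (5.90), Sertoli (5.33) and Leydig markers (5.82), 0 of 3 lay below the range of the other 31 libraries, but levels are shares of 1 total, so this does not exclude it. Fewer late germ cells may also account for the levels, as the round spermatid mean lay at -1.81 from the median of the other libraries while spermatogonia and Sertoli means were above all of them. The 2 explanations cannot be told apart from these values, and the mitochondrial mean (12.1, median of the others 9.83) stays without a tested explanation.

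High AS control replicate 3 held liver transcripts, with ALB at 1770 CPM against a median of 6.05 in the other numbered libraries. ALB was higher across the numbered set, at 4.65 CPM or more, than in plain libraries, with a median of 1.12 CPM and at most 4.69 CPM. Of 29 liver markers other than ALB, fixed before they were looked at, 25 were above all other libraries, which is consistent with RNA or reads from liver, with HPX at 84.8 CPM, APOC3 at 86 CPM and AMBP at 76.8 CPM. Their median fold was 13.9 with 0.5 CPM added to each level, which draws folds toward 1 where a marker had 0 CPM in most other libraries, so its size is not exact. ALB made in the testis without liver material would leave them level, and 27 of 29 were above their median in the other libraries. High AS control replicate 8 came next, with ALB at 66 CPM and a median liver marker 0.54 above the other libraries on the log2 scale with the same addition, and no biological explanation was tested.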

How the results depend on the processing

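The fits with the Leydig marker level, without 2 libraries and without the pigs recorded at 0 mg/kg were chosen only after the results were seen. Apart from the fits that left out each pig in turn, of 127 counts under alternatives, 96 stayed within 1.5 times the reported count and 31 moved. Most of the 96 were counts of 0 that stayed at 0. Of 1507 values of single genes and lists, 1439 kept direction and side of the threshold, 47 no longer passed, 5 newly passed and 16 changed sign. The 47 all belonged to genes called in the main fits, and most of the 1439 had not passed there either. These totals therefore say little about how firm the calls are. Replicate numbers follow accession order and pair no pigs. Sows with pigs in both AS groups (7 of 14) allowed a comparison within families, in which sow as a block or a random effect called 0 genes between AS groups.

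For androstenone (3 genes reported) the count was 9 without a low-count filter, 7 with DESeq2 and 11 with the Leydig marker level, which included all 3. It was 0 with no library set term, with index set, in numbered libraries only, with the sow block, with carcass weight, with the rank of the concentration and without the pigs recorded at 0 mg/kg. For diet (1 gene) it was 0 with the stricter filter, limma voom, no library set term, plain libraries only, numbered libraries only, without lane 7, with sow as a random effect and in 32 pigs without an AS term. For the interaction it was 1 without a filter. For the sire breeding value (2 genes) it was 8 without a filter, 17 with DESeq2, 0 with index set, 0 in plain libraries only, 1 in numbered libraries only, 0 without lane 7, 1 with sow as a random effect, 1 with carcass weight and 4 without the 2 libraries that stood apart. Camera with a preset correlation called 6, 4 and 4 lists for AS, androstenone and diet. A low-count filter removed the diet gene with the stricter filter, with no library set term, in plain libraries only and in 32 pigs without an AS term. It also removed ENSSSCG00000021574 from the androstenone fit without the pigs recorded at 0 mg/kg. Other lower counts in subsets come with fewer pigs, and otherwise the cause was not tested.

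Leaving out 1 pig at a time gave 1 to 4 genes for androstenone, 0 to 1 for diet, 0 to 6 for the sire breeding value and 0 to 0 for the 4 other comparisons. The androstenone count was 1 without High AS chicory replicate 3 or Low AS chicory replicate 6. The diet count was 0 without High AS chicory replicate 4, 5 or 7 or Low AS chicory replicate 3 or 5. The sire breeding value count was 0 without High AS control replicate 8, High AS chicory replicate 7 or Low AS chicory replicate 6, and 6 without Low AS chicory replicate 1.

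Genes that did not pass changed sign as follows. Between AS groups these were NPR1 (0.18), HSD17B3 (0.10) and SPATA18 (-0.08) in numbered libraries only, CYB5A (-0.005) with carcass weight and NR5A1 (0.025) without the 2 libraries that stood apart. For androstenone, NR5A1 had -0.037 with no library set term, -0.041 in plain libraries only, -0.048 without lane 7, -0.079 with carcass weight, -0.021 with the linear concentration, -0.008 with its rank, -0.095 with the Leydig marker level and -0.14 without the pigs recorded at 0 mg/kg. LHCGR had -0.041 in numbered libraries only and CYB5A -0.021 without the pigs recorded at 0 mg/kg. For diet TEK had 0.10 with the sow block. The interaction and AS within chicory could not be fitted in numbered libraries only.

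Further genes that did not pass moved by over 1.5 times. Between AS groups SLC46A3 had 1.04 (SE 0.23) with carcass weight and IGF1 -0.14 (SE 0.32) with no library set term. For androstenone ODF2 had 0.06 (SE 0.13) with the sow block, and with carcass weight FDPS had 0.08 (SE 0.06), SCARB1 0.14 (SE 0.15) and ALAS1 0.15 (SE 0.14). For diet ATF3 had -0.31 (SE 0.26) with the sow block, where TNFRSF12A within control diet had 0.57 (SE 0.44) and KRT4 within chicory 1.65 (SE 0.79). In numbered libraries only, 8 in number, HEY2 had 0.14 (SE 0.44) and TYROBP 0.05 (SE 0.45) for diet.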

Other observations

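The tests of the sow families for ENSSSCG00000021574 and of Leydig against elongating spermatid markers, the Leydig marker covariate and the fit without the pigs recorded at 0 mg/kg were chosen only after the result was seen.

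Leydig marker and elongating spermatid marker levels moved in opposite directions across pigs. In the 23 plain libraries of pigs with an AS group Pearson's r was -0.48 (permutation p = 0.023) and Spearman's rho was -0.50 (permutation p = 0.017). The adjusted p of r was 0.0307 over this 1 relation in 4 overlapping sets of libraries, which are not separate tests. Without the 2 pigs farthest from the Leydig median r was -0.41, and without Low AS chicory replicate 1 it was -0.49. Over all 32 libraries r was -0.48 (permutation p = 0.0041) and rho -0.51 (permutation p = 0.0037). In the 8 numbered libraries r was -0.61 (permutation p = 0.1) and rho -0.62 (permutation p = 0.11), and r was -0.08 without the 2 farthest, so that the relation there rests on those pigs. As levels are shares of 1 total, a sample with more interstitial tissue may show fewer spermatid transcripts, which was not tested apart from a change in either cell type.

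ENSSSCG00000021574 was detected or absent alike in 24 of 29 pairs of pigs from the same sow, 82.8% against 61.4% with shuffled sows (one-sided permutation p = 0.019). Detection may be shared within sow families, and a sequence variant or a gene copy that some families carry is a hypothesis that was not tested here. Sows with more pigs give more of the pairs, so a single family can weigh heavily. The shuffle did not hold index set fixed, and index set partly follows sow, so the test does not separate the influence of family from that of index set.

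SRD5A1 and CYP4B1 rose with androstenone, and the share of Leydig cells, library set and sow families were weighed as explanations. In SEs, the lower of the 2 slopes was 5.85 with the Leydig marker level as a covariate, 5.31 in plain libraries alone and 4.19 with sow as a fixed block. Slopes within 1 SE of 0 were set as the mark of each as the whole cause, and the slopes stayed outside it. Both genes were chosen for their slopes in these pigs, and the marker mean only stands in for the share of Leydig cells. The slopes thus remained in each fit, but none of the explanations is excluded. Plain libraries alone still pool several index sets, and index set held 0.34 of the variance of log2 androstenone (r squared). With index set as a term the slopes were 0.43 (SE 0.10) for SRD5A1 and 0.65 (SE 0.14) for CYP4B1, and neither gene was called. With sow as a block the call ended, as the SE of SRD5A1 went from 0.08 to 0.13 while its slope went from 0.44 to 0.54. A link of both transcripts to androstenone in the testis is a hypothesis found and tested on the same pigs, and the pigs recorded at 0 mg/kg weigh on it, since without them the slopes were 0.35 (SE 0.10) and 0.49 (SE 0.12).

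For the 3 gene counts above 0, chance could not be excluded, each set against 40 splits of the pigs with the real one included. Splits shuffled the tested label among single pigs, without regard to sow, sire or library set. They therefore do not keep the breeding value that pigs of 1 sire share. For androstenone 2 of 40 gave as many as the real 3 (highest other 34), for diet 2 of 40 as many as the real 1 (highest other 1), and for the sire breeding value 2 of 40 as many as the real 2 (highest other 2). For the 4 counts of 0, all 40 of 40 splits give as many by construction, which says nothing about chance. Their highest other split was 1 between AS groups, 0 for the interaction, 182 for AS within control diet and 0 for AS within chicory. The counts of 34 and 182 are each from a single split, and the median of the other splits was 0 genes. They may reflect a structure of the pigs, which was not tested.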
